A study of Arabidopsis thaliana with 30 samples.

How the data were processed

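Whole 7-day seedlings of Arabidopsis thaliana were treated for 6 h in 2 ml of liquid medium with 25 µM GR24 or acetone, per the labels, and RNA was sequenced from the 3′ end (QuantSeq). Of 30 libraries in 10 groups of 3, 18 belong to set 1 (Col-0, PIN1-GFP in Col-0 and pig1) and 12 to set 2 (Col-0 and anac017). The groups follow the titles and the column names. The control columns of set 1 are headed t0 and the labels give acetone for 6 h. The sources do not settle which holds, and clock genes argue against time-matched controls. The columns carry no replicate numbers, so replicates are numbered in column order.

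The deposited tables hold score values: the authors centred and scaled each gene to a z-score, per the values themselves, after a variance-stabilising transform. Per the submitters' processing notes DESeq2 and the TAIR10 reference were used, and no versions are given. The values show that the scaling ran over 24 libraries in set 1 and over 18 in set 2, so 6 further libraries entered each scaling and are not in the tables. How the 15706 and 10843 listed genes had been selected is not stated. Of the identifiers, 15583 and 10798 are in the reference. The tables also give each gene a cluster number (6 and 8 clusters), which was not used.

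Because a score has no fold change, whole reads were recovered from it. The library constants were fitted on genes with tied lowest values, from starting values found in an earlier search of the same tables. The lowest whole numbers were then sought that made every library of a gene whole to within 0.0001 reads. This gave reads for 15652 genes (99.66%) and 10769 genes (99.32%). Tested on simulated data, 100% of 300 genes were recovered correctly in each table, and 0 of the simulated noise genes. The 54 and 74 genes not recovered were left out, among them members of the light-harvesting list, of which 7 of 17 could be tested in set 1 and 10 in set 2. The recovered sums cover the listed genes only and are not the depth of the libraries. Pairs of replicates differed by 2.73 to 19.6 times the counting variance in set 1 and by 5.66 to 46.2 times in set 2 (chi-square per degree of freedom), and no pair was identical.

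Reads were divided by the size factors held in the deposited values, and log2 of the normalised reads plus 1 was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all groups of a table and a moderated, mean-dependent variance. Genes with a mean of at least 10 normalised reads were tested (14266 and 10266), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The test had been planned for counts, before the data were examined, and was changed because the tables hold scores. Differences of the GR24 effect between genotypes were tested as contrasts of 4 groups. Each table was tested alone, and differences of the Col-0 GR24 effect between the sets were not tested. In simulations with 200 changed genes 66.5 to 88.5% of 2-fold and 95 to 100% of 4-fold changes were called, and 2.07 to 7.44% of calls were false. These rates need not hold with more changes or an outlying library, as in Col-0 GR24 of set 2.

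The 24 gene lists were written before the data were examined and tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Calls are given over all genes and adjusted over the list alone. Sets of genes that changed at least 2-fold with GR24 in Col-0 of the other experiment were tested with fry in limma, adjusted over the 3 sets. The fry p-values depend slightly on the order of the groups, which was fixed, and no call changed with it. Named genes are, per comparison, among the 6 largest rises and 6 largest falls with adjusted p under 0.05, at least 5 CPM in the higher group and, for 2 groups, no overlap of libraries, together with up to 4 members of each list with the smallest adjusted p, ANAC017, PIN1 and AOX1A. The DLK2 values for differences of the GR24 effect were added after they were seen. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

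Alternatives left out each library in turn, tested every gene with a read, left out organelle genes, fitted only the groups compared, or estimated the correlation of lists. Others, chosen after the data were seen, used pseudocounts of 0.5 and 5, a mean of 50 reads, size factors by median ratio or from total reads, no moderation, voom weights and the deposited scores. The comparison of pig1 with PIN1-GFP in GR24 was also added then.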

Results

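Transcript levels were measured by 3′ tag sequencing (QuantSeq libraries, which read the 3′ end of each messenger RNA) in 30 libraries of whole Arabidopsis thaliana seedlings. Seedlings were grown for 7 days in long days and then kept for 6 h in liquid medium with 25 µM GR24, a synthetic strigolactone analog, or with its solvent acetone. The libraries form 10 groups of 3, which the labels describe as biological replicates, and belong to 2 experiments. Set 1 (18 libraries) held Col-0, the marker line PIN1-GFP in Col-0 and the line labelled pig1, each with and without GR24. Set 2 (12 libraries) held Col-0 and the line labelled anac017, each with and without GR24. ANAC017 is a membrane-tethered transcription factor that relays mitochondrial signals to the nucleus. In set 1 the control columns are headed t0 although the labels give acetone for 6 h, so these libraries are called control libraries below rather than acetone-treated ones, and what the clock genes showed in them is given with the set 1 comparisons.

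Whole read counts were recovered from the deposited scaled values for 15652 of 15706 genes in set 1 and for 10769 of 10843 genes in set 2. Their sums, which cover the listed genes and not the full library, ran from 5439867 to 11726765 reads in set 1 (highest in pig1 control replicate 1) and from 5317255 to 9441516 in set 2. Genes of the chloroplast genome took 4.01 to 5.41% of these reads in the set 1 control libraries, 2.3 to 3.51% in the set 1 GR24 libraries and 1.36 to 2.74% in set 2. Each experiment was tested only within its own table, since the tables had been normalised separately. Changes are log2 differences ± SE, levels are means ± SD of normalised reads over 3 libraries, and replicates are numbered in the order of the columns. Of 442 changes of named genes that passed the test in comparisons of 2 groups, 439 had every library of one group beyond every library of the other, which the rule for naming genes partly required. The exceptions are stated where they are named.

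The GR24 effect in Col-0 of set 2 addresses which transcripts a strigolactone analog changes in wild-type seedlings. Markers of strigolactone and karrikin response rose. DLK2 (AT3G24420), a paralog of the strigolactone receptor and a standard readout of the pathway, rose by 4.25 ± 0.16 from 285 ± 57 to 5460 ± 1290 reads (adjusted p = 4.1e-09). SMXL2 (AT4G30350), a repressor that the pathway degrades, rose by 2.01 ± 0.14, the karrikin-induced F-box gene KUF1 (AT1G31350) by 1.8 ± 0.21 and the B-box gene BBX20 (AT4G39070) by 1.7 ± 0.16. Of the 9 measured markers 7 rose and none fell (8 and 0 adjusted over the list alone; median 1.39, camera adjusted p = 0.00014, and adjusted p = 0.086 with an estimated correlation). Among 6 measured strigolactone biosynthesis and signalling components, 1 rose and 0 fell, with a median of -0.08 (camera adjusted p = 0.9).

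Detoxification genes were the group with the largest median rise in the same comparison. Of 22 measured members 18 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 2.02 (camera adjusted p = 1.1e-08, and adjusted p = 0.22 with an estimated correlation). The glutathione transferases GSTU7 (AT2G29420) and GSTF8 (AT2G47730) rose by 2.72 ± 0.16 and 2.01 ± 0.14, GSTF8 from 7760 ± 420 to 31300 ± 3020 reads. The glucosyltransferase UGT73B5 (AT2G15480) rose by 2.04 ± 0.16. Defence genes rose as well: FRK1 (AT2G19190), a receptor kinase induced by bacterial flagellin, by 3.61 ± 0.31 from 25.6 ± 7.16 to 335 ± 124 reads, PAD3 (AT3G26830), which makes the antimicrobial camalexin, by 2.63 ± 0.38, and the peroxidase gene PER4 (AT1G14540) by 4.59 ± 0.53. PER4 had 7000, 8530 and 1370 reads in Col-0 GR24 replicates 1 to 3, and without replicate 3 it rose by 5.42. Of 10 measured salicylate and defence genes 9 rose and none fell (9 and 0 adjusted over the list alone; median 1.46, camera adjusted p = 0.0018, and adjusted p = 0.57 with an estimated correlation). For the unfolded protein response of the endoplasmic reticulum, 10 of 11 rose and none fell (10 and 0 adjusted over the list alone; median 0.76, camera adjusted p = 0.002, and adjusted p = 0.57 with an estimated correlation). The chaperone BIP3 (AT1G09080) rose by 3.46 ± 0.57 from 73.9 ± 29.4 to 1040 ± 706 reads and the co-chaperone ERDJ3A (AT3G08970) by 1.53 ± 0.22. BIP3 reads were 1550, 1320 and 232 in GR24 replicates 1 to 3, and the rise was 4.34 without replicate 3. AT3G18250 and the cytochrome P450 gene CYP89A6 (AT1G64940) were among the largest rises, by 4.7 ± 0.48 and 4.25 ± 0.47.

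Falls in the same comparison were found in auxin and root hair genes. Of 16 measured early auxin genes none rose and 8 fell (0 and 8 adjusted over the list alone; median -0.68, camera adjusted p = 1e-04, and adjusted p = 0.086 with an estimated correlation). IAA19 (AT3G15540) and IAA3 (AT1G04240), repressors that auxin itself induces, fell by 2.41 ± 0.25 and 2.34 ± 0.24, IAA19 from 154 ± 13 to 29.1 ± 9.84 reads, and IAA1 (AT4G14560) fell by 1.52 ± 0.18. All 6 measured root hair genes fell (0 and 6 adjusted over the list alone), with a median of -1.66 (camera adjusted p = 0.00014, and adjusted p = 0.36 with an estimated correlation). The cell wall genes PRP3 (AT3G62680) and EXPA18 (AT1G62980) fell by 2.18 ± 0.23 and 1.75 ± 0.17, PRP3 from 1880 ± 300 to 419 ± 99.2 reads. Of 11 auxin transport genes 1 rose and 5 fell (median -0.29, camera adjusted p = 0.075), and PIN1 (AT1G73590), the auxin efflux carrier, was not called, with a change of 0.3 ± 0.38 at 13.5 ± 0.47 against 11.3 ± 4 reads and adjusted p = 0.55. Root tissue markers moved both ways, 4 up and 2 down of 7 (median 0.43, camera adjusted p = 0.92). The largest falls included AT4G33720, of the family of the pathogenesis-related protein PR-1, by 5.77 ± 0.36 from 262 ± 59.6 to 4.08 ± 2.38 reads, the sterol desaturase CYP710A4 (AT2G28860) by 4.28 ± 0.44 and the wall-loosening XTH26 (AT4G28850) by 4.17 ± 0.44.

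The mitochondrial dysfunction stimulon, the set of nuclear genes that rise when mitochondria are impaired, did not rise with GR24 in Col-0 of set 2. Of its 19 measured members 2 rose and 9 fell (2 and 11 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.02, and adjusted p = 0.72 with an estimated correlation). UPOX (AT2G21640), induced by oxidative stress, fell by 1.52 ± 0.28 from 1700 ± 327 to 644 ± 337 reads and the cytokinin response factor CRF6 (AT3G61630) by 1.24 ± 0.22, whereas AT5G14730 rose by 0.91 ± 0.15. The alternative oxidase AOX1A (AT3G22370), the usual reporter of this response, stayed at 5740 ± 722 against 6940 ± 573 reads (change -0.28 ± 0.14, adjusted p = 0.12). Without Col-0 GR24 replicate 1 the camera call of the stimulon was lost (adjusted p = 0.063).

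In all, 2575 genes were higher and 1683 lower with GR24 among 10266 tested (limma, adjusted p under 0.05), 787 and 544 of them at least 2-fold. With size factors from total reads 40.1% of 4186 calls were higher in place of 60.5%, and the median change of all genes moved from 0.07 to -0.09. Col-0 GR24 replicate 3 stood apart from its group. The mean of the salicylate and defence list was 0.46 in it against 2.3 and 2.33 in the other GR24 replicates, and that of the hypoxia list 0.01 against 1.85 and 1.45, each relative to the mean of all libraries. Of 11 measured hypoxia genes 1 rose (median 0.82, camera adjusted p = 0.33), and of 13 heat shock genes 6 rose (median 0.86, camera adjusted p = 0.075). Without Col-0 GR24 replicate 1 the count of called genes was 2832. Of 7 measured clock genes 2 rose, with a median of 0.24 (camera adjusted p = 0.36), and the 7 touch genes gave 2 rises and 1 fall (camera adjusted p = 0.77).

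**Figure D1:**
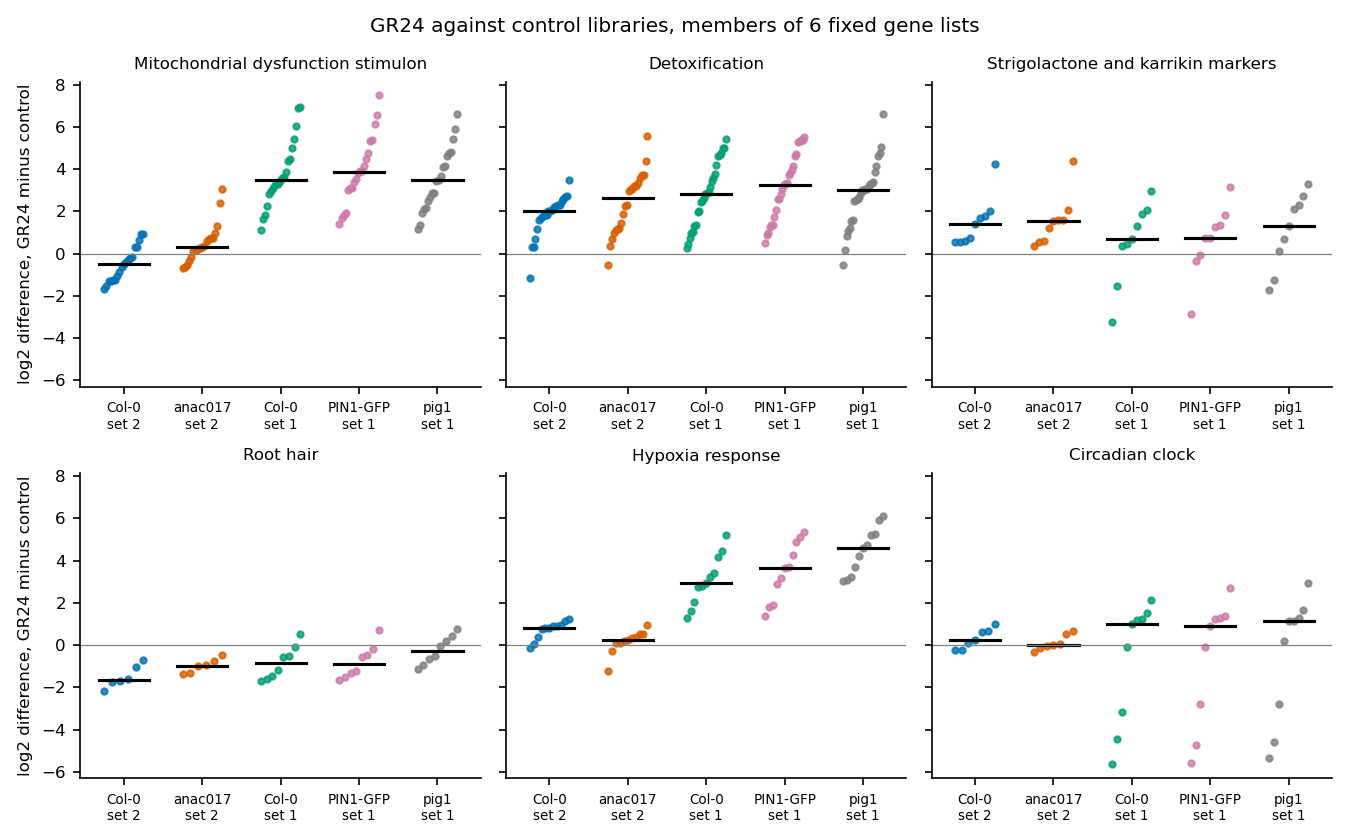
Log2 difference between GR24 and control libraries (vertical axis) of the members of 6 gene lists, by genotype and experiment; points are genes and bars medians. The mitochondrial dysfunction stimulon has a median of -0.47 in Col-0 of set 2 and 3.5 in Col-0 of set 1.

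The comparison of anac017 with Col-0 in acetone addresses how the line labelled anac017 differs without GR24. All 19 measured members of the mitochondrial dysfunction stimulon were lower in anac017, with a median of -2.85 (all 19 adjusted over the list alone, camera adjusted p = 2.4e-18, and adjusted p = 0.13 with an estimated correlation). UGT74E2 (AT1G05680), a glucosyltransferase acting on an auxin precursor, fell by 4.44 ± 0.24 from 6700 ± 815 to 314 ± 85.1 reads (adjusted p = 6.5e-08). AOX1A fell by 2.41 ± 0.14 from 6940 ± 573 to 1320 ± 247 reads, and its paralog AOX1D (AT1G32350) by 6.84 ± 0.57 from 727 ± 265 to 5.37 ± 2.38 reads. The transcription factor NAC013 (AT1G32870) fell by 1.76 ± 0.13 and the external NADH dehydrogenase NDB2 (AT4G05020) by 1.93 ± 0.23. In the alternative respiratory pathway 4 of 7 genes were lower and 1 higher (4 and 1 adjusted over the list alone; median -0.59, camera adjusted p = 0.0099, and adjusted p = 0.33 with an estimated correlation). Of 22 measured detoxification genes 20 were lower and none higher (20 and 0 adjusted over the list alone; median -1.85, camera adjusted p = 2.9e-13, and adjusted p = 0.13 with an estimated correlation). CYP81D8 (AT4G37370) was lower, at -3.36 ± 0.25, and GSTU9 (AT5G62480) at -3.7 ± 0.28.

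Other groups also differed between the genotypes in acetone. Of 7 touch-induced genes 5 were lower in anac017 and none higher (6 and 0 adjusted over the list alone; median -0.86, camera adjusted p = 0.002, and adjusted p = 0.34 with an estimated correlation). The zinc finger gene ZAT12 (AT5G59820) was at 384 ± 70.9 against 1480 ± 297 reads (log2 difference -1.94 ± 0.21) and the calmodulin-like TCH3 (AT2G41100) at 5530 ± 1360 against 9900 ± 613. Of 11 hypoxia genes 3 were lower (3 adjusted over the list alone, median -1.11, camera adjusted p = 0.0099, and adjusted p = 0.68 with an estimated correlation); the camera call was lost without anac017 acetone replicate 3 (adjusted p = 0.053). HRE2 (AT2G47520), an ethylene response factor of the hypoxia response, fell by 3.52 ± 0.35. Of 16 early auxin genes 2 were higher and 9 lower (2 and 10 adjusted over the list alone; median -0.74, camera adjusted p = 0.0099, and adjusted p = 0.33 with an estimated correlation), with GH3.2 (AT4G37390) lower, at -1.78 ± 0.33, and IAA3 higher by 1.47 ± 0.24. Light-harvesting genes, used as a marker of shoot tissue, were higher for 9 of 10 (10 adjusted over the list alone, median 0.56, camera adjusted p = 0.00022, and adjusted p = 0.48 with an estimated correlation). LHCB2.1 (AT2G05100) rose by 0.61 ± 0.12. Among the largest differences, the orphan gene QQS (AT3G30720) was higher by 3.13 ± 0.26 and the lectin gene JAX1 (AT1G58160) by 3 ± 0.39. AT3G01345 was lower, at -7.13 ± 0.43.

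Transcript tags of ANAC017 (AT1G34190) were higher, not lower, in libraries labelled anac017, at 1460 ± 59.9 against 204 ± 26 reads (log2 difference 2.85 ± 0.12, adjusted p = 7.5e-09). A 3′ tag does not show whether a full-length transcript was made. The clock list had 1 gene higher of 7 (4 adjusted over the list alone, median 0.34, camera adjusted p = 0.048, and adjusted p = 0.6 with an estimated correlation). ELF4 (AT2G40080) was higher by 0.96 ± 0.16, and the camera call was lost without Col-0 acetone replicate 1 (0.054), 2 (0.055) or 3 (0.057), or anac017 acetone replicate 2 (0.072). In total 1469 genes were higher and 1472 lower of 10266 (limma), 362 and 477 at least 2-fold. Without Col-0 acetone replicate 3 the total was 1845 in place of 2941. With size factors from total reads 63.6% of 2870 calls were higher in place of 49.9%.

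**Figure D2:**
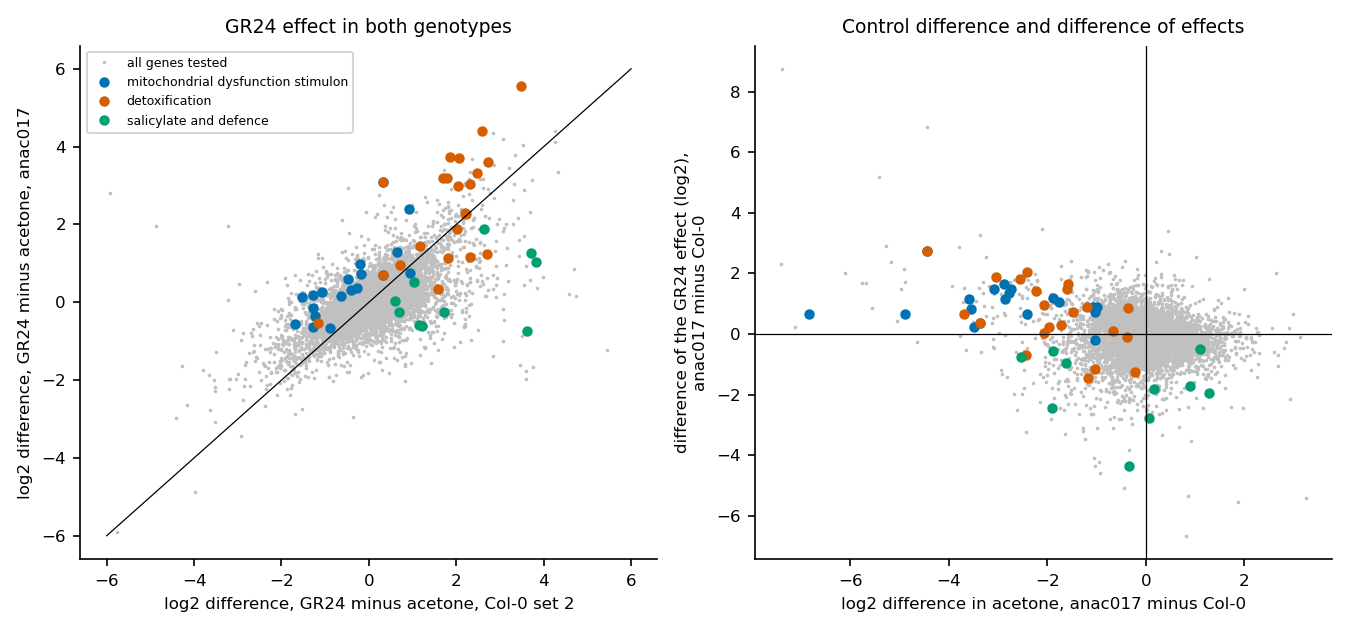
Log2 GR24 effect in anac017 against that in Col-0 of set 2 (left), and difference of the effects against the difference between the genotypes in acetone (right); points are genes, with the stimulon, detoxification and salicylate and defence lists in colour. The stimulon has a median of -2.85 on the right horizontal axis. The right axes share the acetone libraries, which favours a negative slope.

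The GR24 effect within anac017 addresses what the analog changes in the line labelled anac017. DLK2 rose by 4.4 ± 0.16 from 249 ± 26.8 to 5280 ± 267 reads, SMXL2 by 1.58 ± 0.14, KUF1 by 2.05 ± 0.21 and BBX20 by 1.6 ± 0.16. Of 9 strigolactone and karrikin markers 7 rose and none fell (8 and 0 adjusted over the list alone; median 1.56, camera adjusted p = 5.5e-07, and adjusted p = 0.036 with an estimated correlation). Detoxification genes rose for 17 of 22 (20 adjusted over the list alone, median 2.63, camera adjusted p = 1.3e-17, and adjusted p = 0.06 with an estimated correlation). GSTU24 (AT1G17170) rose by 4.4 ± 0.26 from 506 ± 235 to 9920 ± 1120 reads, GSTU7 by 3.6 ± 0.16, and the xenobiotic-induced CYP81D11 (AT3G28740) by 5.55 ± 0.34 from 22.5 ± 15.4 to 969 ± 38.2 reads. UGT74E2 rose by 3.08 ± 0.24 to 2610 reads, below the 6700 of Col-0 in acetone. In the stimulon 6 of 19 rose and none fell (8 and 0 adjusted over the list alone; median 0.31, camera adjusted p = 0.012, and adjusted p = 0.55 with an estimated correlation), a call lost without anac017 GR24 replicate 1 (adjusted p = 0.055). NAC013 rose by 0.61 ± 0.13 and NDB2 by 1.92 ± 0.23, whereas AOX1A changed by 0.37 ± 0.14 and was not called (adjusted p = 0.066). The alternative respiratory pathway gave 3 rises of 7 (4 adjusted over the list alone, median 0.5, camera adjusted p = 0.012, and adjusted p = 0.3 with an estimated correlation).

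Flavonoid genes rose with GR24 in anac017. Of 9 measured members 7 rose and none fell (7 and 0 adjusted over the list alone; median 0.97, camera adjusted p = 3.3e-05, and adjusted p = 0.14 with an estimated correlation), among them chalcone synthase CHS (AT5G13930) by 1.78 ± 0.12 from 760 ± 114 to 2580 ± 75.5 reads and FLS1 (AT5G08640) by 1.58 ± 0.18. The iron deficiency regulator BHLH39 (AT3G56980) rose by 2.22 ± 0.29, and 3 of 9 iron genes rose (4 adjusted over the list alone, median 0.4, camera adjusted p = 0.018, and adjusted p = 0.3 with an estimated correlation). Of 13 heat shock genes 6 rose (6 adjusted over the list alone, median 0.53, camera adjusted p = 0.018, and adjusted p = 0.55 with an estimated correlation); without anac017 acetone replicate 3 this call was lost (0.13). The chaperone HSP70-4 (AT3G12580) rose by 1.24 ± 0.15 and the coactivator MBF1C (AT3G24500) by 1.04 ± 0.12. Falls were again found in auxin and root hair genes. IAA29 (AT4G32280) fell by 2.67 ± 0.3, IAA19 by 1.6 ± 0.25, PRP3 by 1.32 ± 0.23, EXPA18 by 0.95 ± 0.17, and the root aquaporin TIP2-3 (AT5G47450) by 2.76 ± 0.35 from 1080 ± 31.6 to 167 ± 69.6 reads. Early auxin genes fell for 7 of 16 (8 adjusted over the list alone, with 1 rise; median -0.62, camera adjusted p = 0.0045, and adjusted p = 0.17 with an estimated correlation). Root hair genes fell for 4 of 6 (6 adjusted over the list alone, median -0.98, camera adjusted p = 0.0022, and adjusted p = 0.34 with an estimated correlation). The light-harvesting list had 3 of 10 lower (5 adjusted over the list alone, median -0.3, camera adjusted p = 0.018, and adjusted p = 0.55 with an estimated correlation), a call lost without anac017 acetone replicate 3 (0.12) or anac017 GR24 replicate 3 (0.068). Called genes numbered 1300 higher and 1026 lower (limma), 444 and 305 at least 2-fold. Without anac017 GR24 replicate 2 the total was 1474 in place of 2326.

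The difference of the GR24 effect between anac017 and Col-0 addresses which responses to the analog differ in that line. DLK2 was not called, with a difference of 0.16 ± 0.23 (adjusted p = 0.7). Rises that were larger in anac017 were found for UGT74E2 (difference 2.75 ± 0.34, adjusted p = 0.0019), GSTU1 (AT2G29490) (1.5 ± 0.21, adjusted p = 0.0049) and AT5G14730 (1.48 ± 0.21, adjusted p = 0.0053). With GR24, UGT74E2 still had 2330, 2760 and 2720 reads in anac017 against 5640, 8420 and 12400 in Col-0. In the mitochondrial dysfunction stimulon the difference was higher for 5 of 19 genes and lower for none (12 and 0 over the list alone; median 0.89, camera adjusted p = 2.3e-09; 0.4 with an estimated correlation). In the detoxification list it was higher for 6 of 22 and lower for 0 (9 and 2 over the list alone; median 0.69, camera 0.00013 and 0.4). Both lists were lower in anac017 in acetone, and these libraries enter the difference with the opposite sign. The GR24 effect was lower in anac017 for FRK1, with a difference of -4.37 ± 0.44 (adjusted p = 0.00065), and for AT2G44370 and AT2G17740, with -4.37 ± 0.54 and -4.08 ± 0.51. FRK1 had 335 ± 124 against 25.6 ± 7.16 reads in Col-0 with and without GR24, and 11.1 against 19.9 in anac017. The salicylate and defence list had 1 of 10 lower (5 over the list alone, median -1.77, camera 0.00044 and 0.41). The unfolded protein response had 2 of 11 lower (9 over the list alone, median -0.71, camera 0.00011 and 0.4). Of 9 flavonoid genes 0 were called (0 over the list alone, median 0.83, camera 0.004 and 0.4). AOX1A differed by 0.65 ± 0.19 and was not called (adjusted p = 0.093).

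The number of genes behind this difference rested on single libraries. With all 12 libraries 66 genes had a larger and 112 a smaller GR24 effect in anac017 (178 of 10266, limma; 2320 at an unadjusted p under 0.05). Without Col-0 GR24 replicate 3, the library that stood apart, the count was 2085. Without each other library it was 20, 38 and 12 for Col-0 acetone replicates 1 to 3, 26 and 18 for Col-0 GR24 replicates 1 and 2, 44, 68 and 115 for anac017 acetone replicates 1 to 3 and 23, 16 and 63 for anac017 GR24 replicates 1 to 3. The other test, on voom weights, called 61 genes, and limma without moderation and limma on the deposited scaled values called 0. With size factors from total reads 52.9% of 187 calls were higher in place of 37.1%, with size factors by median ratio 49.4% of 176, and with total reads the median over all genes moved from -0.08 to 0.03. Further lists passed camera: abscisic acid genes at 0.44 (0.022; 0.4 with an estimated correlation; 1 called over the list alone), early auxin genes at 0.31 (0.017 and 0.4), root hair genes at 0.47 (0.032; 0.61; 1 called over the list alone) and sugar starvation genes at -1.3 (0.022; 0.42; 4 called over the list alone), all with 0 genes called over all genes. These calls were lost without Col-0 acetone replicate 2 (abscisic acid, 0.061), Col-0 acetone replicate 1 (auxin, 0.06; root hair, 0.091), Col-0 GR24 replicate 2 (root hair, 0.13), anac017 acetone replicate 1 (root hair, 0.16), anac017 GR24 replicate 3 (root hair, 0.062) and anac017 acetone replicate 3 (0.065, 0.069, 0.056 and 0.069 in the order of the lists). Over 2596 genes that changed at least 2-fold with GR24 in Col-0 of set 1, the GR24 effect in anac017 minus that in Col-0 averaged -0.05 in the direction of that change (51.4% smaller, fry adjusted p = 0.95, and 0.0019 for change in either direction). If the heading t0 holds, that set mixes in time and incubation, so it cannot tell whether the GR24 response was kept.

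**Figure D3:**
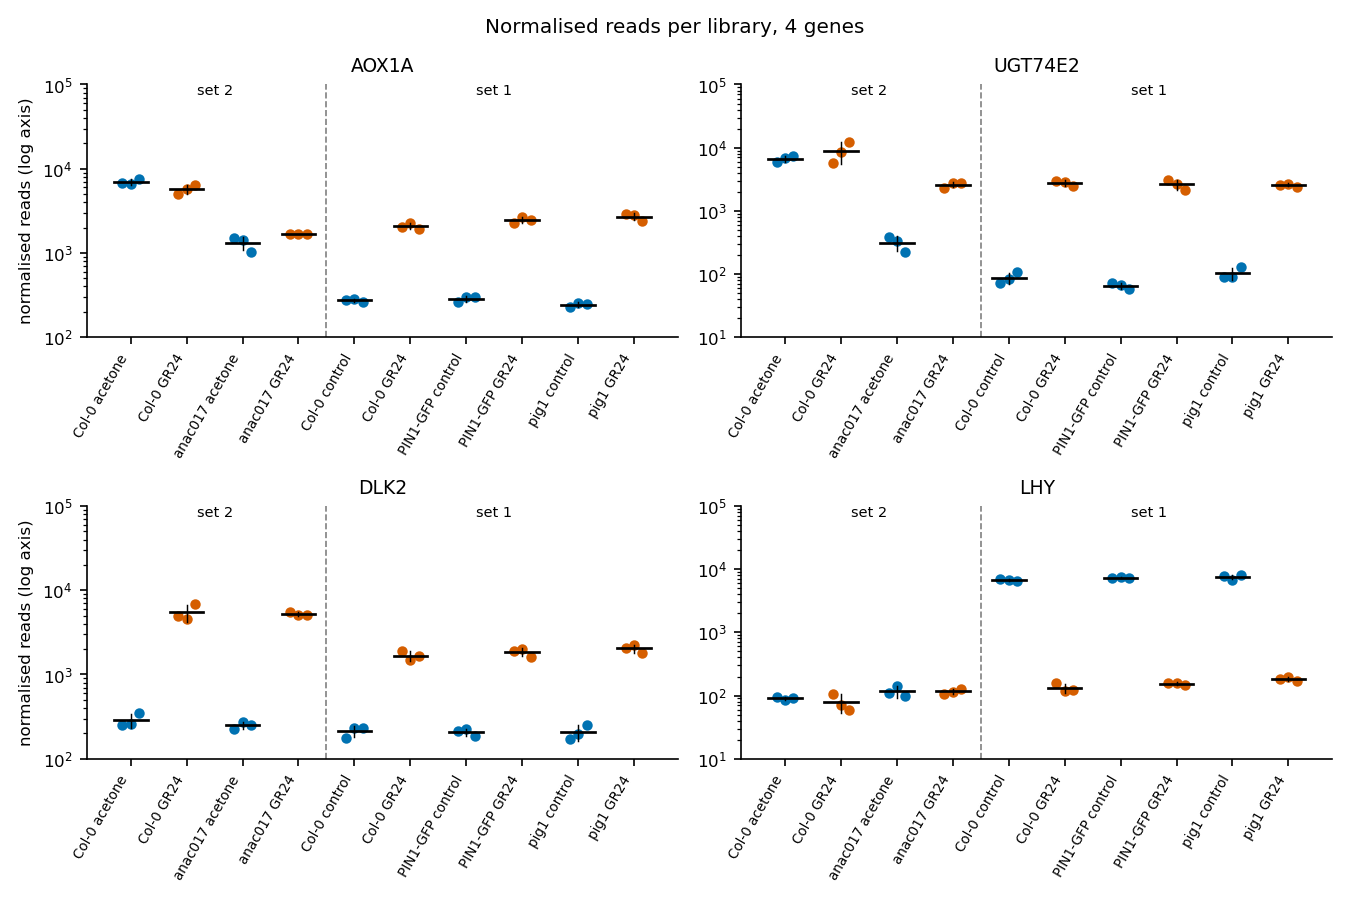
Normalised reads per library (log axis) of AOX1A, UGT74E2, DLK2 and LHY in the 10 groups; points are libraries, bars the mean and lines 1 SD, and the 2 experiments were normalised separately. AOX1A lies at 6940 in Col-0 acetone of set 2 and at 272 in the Col-0 control of set 1.

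In set 1 the GR24 libraries differed from the control libraries in clock genes, beside every other change given for this set. LHY (AT1G01060), a morning-phased clock gene, fell by 5.65 ± 0.1 in Col-0 from 6660 ± 245 to 132 ± 20.7 reads (adjusted p = 4.9e-18), and it fell by 5.56 ± 0.1 in PIN1-GFP and fell by 5.36 ± 0.1 in pig1. CCA1 (AT2G46830) fell by 4.46 ± 0.18, 4.73 ± 0.18 and 4.57 ± 0.18 in the same order, and the daytime-phased PRR7 (AT5G02810) rose by 1.54 ± 0.12 in Col-0. In each genotype 5 of 9 clock genes rose and 3 fell (camera adjusted p = 0.82 in Col-0, 0.82 in PIN1-GFP and 0.59 in pig1). As counts scaled to the reads of the 9032 genes shared by the tables (CPM), LHY stood at 1510 ± 44.1 in the Col-0 controls and 32.1 ± 4.25 with GR24 in set 1, and at 13.3 ± 0.762 and 10.2 ± 3.06 in set 2, a level not tested across the tables. The light-induced ELIP2 (AT4G14690) fell by 6.83 ± 0.16 in PIN1-GFP and by 6.07 ± 0.16 in pig1, and the CONSTANS-like COL2 (AT3G02380) by 5.65 ± 0.19 in PIN1-GFP.

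The contrast of GR24 with control libraries in Col-0 of set 1 addresses the same question as in set 2 only if the labels hold. If the heading t0 holds, time of collection and incubation change together with GR24 in every set 1 GR24 effect. All 20 measured members of the mitochondrial dysfunction stimulon rose, with a median of 3.5 (all 20 adjusted over the list alone, camera adjusted p = 9.1e-14, and adjusted p = 0.0046 with an estimated correlation). AOX1A rose by 2.94 ± 0.1 from 272 ± 12.2 to 2090 ± 179 reads and UPOX by 4.37 ± 0.13 from 39.2 ± 2.89 to 835 ± 93.8 reads. Of 26 detoxification genes 23 rose and none fell (23 and 0 adjusted over the list alone; median 2.83, camera adjusted p = 9.1e-14, and adjusted p = 0.02 with an estimated correlation). UGT74E2 rose by 4.99 ± 0.16, GSTF6 (AT1G02930) by 4.2 ± 0.13 and the alkenal reductase AER (AT5G16970) by 3.57 ± 0.12. All 11 hypoxia genes rose (11 adjusted over the list alone, median 2.93, camera adjusted p = 2.4e-05, and adjusted p = 0.27 with an estimated correlation), including pyruvate decarboxylase PDC1 (AT4G33070) by 4.44 ± 0.31 and the oxygen sensor PCO1 (AT5G15120) by 2.93 ± 0.20. Of 11 heat shock genes 10 rose (10 adjusted over the list alone, median 3.88, camera adjusted p = 2.5e-05, and adjusted p = 0.2 with an estimated correlation). HSP70-4 rose by 2.84 ± 0.15 from 1110 ± 18.4 to 8010 ± 839 reads. Touch genes rose for 5 of 7 (5 adjusted over the list alone, median 1.81, camera adjusted p = 0.024, and adjusted p = 0.2 with an estimated correlation). Salicylate and defence genes rose for 8 of 11 (10 adjusted over the list alone, median 1.28, camera adjusted p = 0.019, and adjusted p = 0.27 with an estimated correlation), with WRKY70 (AT3G56400) up by 1.99 ± 0.17. Strigolactone and karrikin markers gave 5 rises and 2 falls of 9 (6 and 2 adjusted over the list alone; median 0.71, camera adjusted p = 0.062); DLK2 rose by 2.98 ± 0.15 from 212 ± 32.7 to 1670 ± 213 reads and SMXL2 by 1.86 ± 0.15.

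Flavonoid, mitotic and light-harvesting genes fell in the same comparison. Of 14 flavonoid genes 11 fell and 1 rose (11 and 2 adjusted over the list alone; median -1.98, camera adjusted p = 3.1e-05, and adjusted p = 0.2 with an estimated correlation), with DFR (AT5G42800) down by 6.93 ± 0.53 from 418 ± 145 to 3.45 ± 3.44 reads and FLS1 by 2.11 ± 0.08. All 8 mitotic genes, a marker of meristems, fell (8 adjusted over the list alone, median -1.29, camera adjusted p = 0.0025, and adjusted p = 0.27 with an estimated correlation), such as the cyclin CYCA1-1 (AT1G44110) by 2.17 ± 0.21 and the cytokinesis gene KNOLLE (AT1G08560) by 2 ± 0.21. Light-harvesting genes fell for 5 of 7 (5 adjusted over the list alone, median -0.44, camera adjusted p = 0.04, and adjusted p = 0.4 with an estimated correlation), LHCB6 (AT1G15820) by 1 ± 0.09. Root tissue markers fell for 7 of 11 and rose for 1 (8 and 1 adjusted over the list alone; median -0.59, camera adjusted p = 0.04, and adjusted p = 0.27 with an estimated correlation); CASP5 (AT5G15290), of the root endodermis, fell by 3.46 ± 0.35. The unfolded protein response had 7 of 11 higher (7 adjusted over the list alone, median 0.28, camera adjusted p = 0.04, and adjusted p = 0.27 with an estimated correlation). Of 13 jasmonate genes 10 were higher and 2 lower (10 and 2 adjusted over the list alone; median 0.87, camera adjusted p = 0.04, and adjusted p = 0.48 with an estimated correlation), with the repressor JAZ1 (AT1G19180) up by 2.5 ± 0.27. Camera calls were lost without Col-0 control replicate 1 (unfolded protein 0.064, jasmonate 0.05, light-harvesting 0.05, root tissue 0.064), Col-0 control replicate 2 (jasmonate 0.058), Col-0 GR24 replicate 1 (jasmonate 0.099) and Col-0 GR24 replicate 2 (light-harvesting 0.063, root tissue 0.054). PIN1 fell by 1.08 ± 0.3 at 20.6 ± 9.39 against 42.4 ± 12.2 reads, with 2 of 3 GR24 libraries below all controls. Strigolactone biosynthesis and signalling components gave 2 rises and 3 falls of 7 (median -0.08, camera adjusted p = 0.55). In total 4609 genes were higher and 4655 lower of 14266 (limma), 1687 and 1969 at least 2-fold.

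The same contrast in PIN1-GFP and pig1 gave 4963 and 5048 genes higher and 4868 and 4940 lower. Stimulon genes rose for all 20 measured members in both, with medians of 3.87 (camera adjusted p = 7.2e-13; 0.0062 with an estimated correlation) and 3.47 (1.7e-11 and 0.0094). AOX1A rose by 3.11 ± 0.1 in PIN1-GFP and by 3.46 ± 0.1 in pig1, from 243 ± 15.1 to 2700 ± 272 reads. DLK2 rose by 3.14 ± 0.15 and 3.31 ± 0.15 in the same order. Detoxification genes rose for 25 of 26 in PIN1-GFP (median 3.25, camera adjusted p = 8.6e-14; 0.019 with an estimated correlation). In pig1 it was 24 of 26 (median 3.03, camera 1.7e-11 and 0.04). All 11 hypoxia genes rose in both, with medians of 3.63 (camera adjusted p = 2.5e-05; 0.23 with an estimated correlation) and 4.6 (1e-06 and 0.18). The hypoxia repressor LBD41 (AT3G02550) rose by 4.6 ± 0.26 in pig1 from 163 ± 40.9 to 3880 ± 196 reads, and the calmodulin-like CML38 (AT1G76650) by 7.16 ± 0.39. Heat shock genes had medians of 4.14 (camera adjusted p = 4.3e-05; 0.23 with an estimated correlation) in PIN1-GFP and 1.1 (0.0036 and 0.27) in pig1, and touch genes 1.94 (0.0048 and 0.14) and 3.13 (0.00048 and 0.044). Flavonoid genes fell, 10 of 14 in PIN1-GFP (median -1.7, camera adjusted p = 0.001; 0.23 with an estimated correlation) and 11 of 14 in pig1 (median -2.32, 2.3e-05 and 0.15).

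Further lists passed camera in PIN1-GFP and pig1 but not with an estimated correlation. The medians in PIN1-GFP and pig1 were -1.15 (camera adjusted p = 0.0081, and adjusted p = 0.29 with an estimated correlation) and -1.45 (0.003 and 0.27) for mitotic genes, -0.68 (0.0045 and 0.28) and -0.78 (0.0037 and 0.27) for light-harvesting genes, 0.66 (0.0064 and 0.23) and 0.59 (0.0021 and 0.15) for the unfolded protein response. They were 1.11 (camera adjusted p = 0.0081; 0.35 with an estimated correlation) and 2.02 (0.00056 and 0.27) for jasmonate genes and 1.72 (0.0044 and 0.23) and 1.2 (0.0035 and 0.27) for salicylate and defence genes, and the strigolactone and karrikin markers passed in pig1 at 1.29 (0.036 and 0.15). KNOLLE fell by 2.2 ± 0.21 in PIN1-GFP, JAZ1 rose by 3.35 ± 0.27, and the defence regulator WRKY33 (AT2G38470) rose by 3.53 ± 0.25 in pig1. PIN1 fell by 1.28 ± 0.3 in pig1, and by 0.83 ± 0.3 in PIN1-GFP, where the call was lost without control replicate 1 (adjusted p = 0.063) or GR24 replicate 3 (0.058). Of the genes higher in Col-0 with GR24, 3879 were also higher in PIN1-GFP against 1603 by chance, and 3938 were lower in both against 1588.

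The GR24 effects in Col-0 of set 1 and of set 2 were set side by side without a test, since the tables were normalised separately. Among 8583 genes tested in both, 1301 were higher in both experiments against 841 by chance and 645 lower in both against 479. Another 390 were higher in set 1 and lower in set 2, with 532 by chance, and 337 the reverse, with 758 (Pearson's r = 0.31 and Spearman's rho = 0.33 across genes, which are not independent replicates). Control levels differed most in the mitochondrial dysfunction stimulon. As a share of the reads of shared genes its median was 4.54 log2 units higher in the Col-0 acetone libraries of set 2 than in the Col-0 controls of set 1 (20 of 20 members; 4.33 to 4.81 over 9 pairs of libraries). AOX1A had 61.7 ± 2.84 CPM in the set 1 control, 510 ± 43.2 with GR24 in set 1, 1020 ± 71.7 in acetone of set 2 and 745 ± 118 with GR24 in set 2. DLK2 had 48.1 ± 7.96, 406 ± 45.1, 41.7 ± 7.71 and 712 ± 196 in the same order. Heat shock genes were higher by a median of 2.75 in the set 2 controls (13 of 13) and hypoxia genes by 2.68 (11 of 11), while flavonoid genes were lower, at -3.57, and root tissue markers at -1.76.

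The comparison of PIN1-GFP with Col-0 in control libraries addresses whether the marker line differs from wild type, and few genes did. QQS was higher by 6.76 ± 0.21 from 14.6 ± 5.26 to 1650 ± 238 reads (adjusted p = 1.5e-13). ATMRD1 (AT1G53480) was lower, at -6.38 ± 0.63, as were ASG1 (AT5G17640) at -3.93 ± 0.25 and the transporter PDR9 (AT3G53480) at -0.56 ± 0.08, the last from 880 ± 45 to 595 ± 34 reads. PIN1 tags were at 94.8 ± 8.28 against 42.4 ± 12.2 reads, a difference of 1.18 ± 0.3 that was not called (adjusted p = 0.19). In total 7 genes were higher and 6 lower of 14266 (limma), 1004 had an unadjusted p under 0.05, and a fit of these 6 libraries alone called 85. On the deposited scaled values limma called 6. Camera passed for small shifts of the detoxification list (median -0.24, adjusted p = 7.7e-06, and adjusted p = 0.53 with an estimated correlation), flavonoid genes (-0.31; 0.004; 0.64) and heat shock genes (-0.32; 0.044; 0.65), all with 0 genes called. Flavonoid genes lost the call without Col-0 control replicate 3 (0.078), and heat shock genes without PIN1-GFP control replicates 1 (0.12) or 2 (0.096) or Col-0 control replicate 2 (0.24).

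The GR24 effect differed between PIN1-GFP and Col-0 for 3 genes (limma; 1540 at an unadjusted p under 0.05). Voom weights, size factors from total reads and limma without moderation each called 1, and the deposited scaled values 0. The genes were NANA (AT3G12700) (difference 0.85 ± 0.12, adjusted p = 0.011), ARGAH2 (AT4G08870) (1.05 ± 0.17, adjusted p = 0.042) and ELIP2 (-1.4 ± 0.23, adjusted p = 0.046). NANA lost its call without PIN1-GFP control replicates 2 (0.06) or 3 (0.053) or Col-0 control replicate 3 (0.051). ARGAH2 lost it without PIN1-GFP control replicates 1 to 3 (0.093, 0.072 and 0.084), Col-0 control replicates 1 (0.061) and 3 (0.092), PIN1-GFP GR24 replicates 1 (0.094) and 2 (0.097) and Col-0 GR24 replicate 2 (0.052). ELIP2 lost it without PIN1-GFP control replicates 1 to 3 (0.093, 0.14 and 0.12), Col-0 control replicates 1 to 3 (0.061, 0.11 and 0.092), PIN1-GFP GR24 replicates 1 (0.11) and 2 (0.097) and Col-0 GR24 replicates 2 (0.077) and 3 (0.091). The count was 0 without PIN1-GFP control replicates 2 or 3 or Col-0 control replicate 3, and 1 without PIN1-GFP control replicate 1, Col-0 control replicate 1 or PIN1-GFP GR24 replicates 1 or 2. It was 28 without PIN1-GFP GR24 replicate 3 and 8 without Col-0 GR24 replicate 1. Camera passed for the detoxification list at a median of 0.32 (adjusted p = 0.00044, and adjusted p = 0.42 with an estimated correlation), flavonoid genes at 0.43 (0.00044 and 0.42), light-harvesting genes at -0.24 (0.0044 and 0.48), the unfolded protein response at 0.19 (0.044 and 0.48), salicylate and defence genes at 0.4 (0.022 and 0.48) and touch genes at 0.47 (0.02 and 0.42), with 0 members called in each. The unfolded protein call was lost without PIN1-GFP control replicate 2 (0.12), Col-0 control replicates 2 (0.13) and 3 (0.06), PIN1-GFP GR24 replicates 1 (0.16) and 2 (0.062) and Col-0 GR24 replicate 2 (0.15). The salicylate call was lost without Col-0 control replicate 1 (0.12), PIN1-GFP GR24 replicate 3 (0.055) and Col-0 GR24 replicate 1 (0.26), and the touch call without PIN1-GFP GR24 replicate 2 (0.086) and Col-0 GR24 replicate 3 (0.056).

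The comparison of pig1 with PIN1-GFP and with Col-0 in control libraries addresses what the pig1 line changes without GR24. Root hair genes were lower in pig1. PRP3 was lower than in PIN1-GFP, at -1.26 ± 0.22 (adjusted p = 0.0022), and EXPA18 at -1.26 ± 0.23, with 126 ± 5.46 against 304 ± 38 reads. Against Col-0, PRP3 was lower, at -1.39 ± 0.22, and RSL2 (AT4G33880), a regulator of root hair growth, at -1.46 ± 0.22. Of 8 root hair genes 6 were lower against PIN1-GFP (6 adjusted over the list alone, median -1.14, camera adjusted p = 1e-08, and adjusted p = 0.066 with an estimated correlation). Against Col-0 it was 7 of 8 (8 adjusted over the list alone, median -1.29, camera adjusted p = 9.4e-11, and adjusted p = 0.034 with an estimated correlation). Root tissue markers had medians of -0.29 against PIN1-GFP (camera adjusted p = 0.2; 1 of 11 lower, 4 lower and 1 higher over the list alone) and -0.34 against Col-0 (0.094; 0 lower, 3 lower and 0 higher over the list alone). Some detoxification and flavonoid genes were higher, fewer against Col-0 than against PIN1-GFP. GSTF6 rose by 2.07 ± 0.13 against PIN1-GFP and 1.84 ± 0.13 against Col-0, and chalcone isomerase CHI (AT3G55120) by 0.61 ± 0.11 against PIN1-GFP. Against PIN1-GFP 11 of 26 detoxification genes were higher (13 adjusted over the list alone, median 0.53, camera adjusted p = 1e-08, and adjusted p = 0.066 with an estimated correlation). So were 9 of 14 flavonoid genes (12 adjusted over the list alone, median 0.65, camera adjusted p = 1.8e-08, and adjusted p = 0.066 with an estimated correlation). Against Col-0 the counts were 3 of 26 (5 adjusted over the list alone, median 0.24, camera adjusted p = 0.009, and adjusted p = 0.56 with an estimated correlation) and 3 of 14 (10 adjusted over the list alone, median 0.48, camera adjusted p = 3e-04, and adjusted p = 0.37 with an estimated correlation), in the same order. The chaperone gene HSP70-4 and the small heat shock protein gene HSP17.6II (AT5G12020) were higher by 1.14 ± 0.15 and 2.25 ± 0.41 against PIN1-GFP and by 0.76 ± 0.15 and 2.8 ± 0.41 against Col-0. Of 11 heat shock genes 3 were higher against PIN1-GFP (7 adjusted over the list alone, median 0.84, camera adjusted p = 7.2e-06, and adjusted p = 0.2 with an estimated correlation). Compared with Col-0, 3 of 11 were higher (4 adjusted over the list alone, median 0.72, camera adjusted p = 0.009, and adjusted p = 0.56 with an estimated correlation).

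Single genes with large differences in pig1 against PIN1-GFP included AT5G52970, lower at -3.59 ± 0.2 (78.6 ± 33.4 against 907 ± 21.4 reads), and AT5G14790, lower at -3.01 ± 0.22. The myrosinase-family gene BGLU22 (AT1G66280) was lower, at -2.88 ± 0.47. The pathogen-responsive PCC1 (AT3G22231) was higher by 4.75 ± 0.46 from 6.64 ± 0.488 to 213 ± 77.7 reads. The lipoxygenase LOX2 (AT3G45140) was higher by 1.5 ± 0.2 and WRKY70 by 0.99 ± 0.17. AOX1A did not differ by the test, at -0.24 ± 0.1 against PIN1-GFP (adjusted p = 0.15) and -0.16 ± 0.1 against Col-0 (0.35). PIN1 was at 0.19 ± 0.3 against PIN1-GFP (adjusted p = 0.76). Against Col-0 it was higher by 1.37 ± 0.3, a call lost without Col-0 control replicate 1 (0.076) or pig1 control replicate 1 (0.051). QQS and ATMRD1 differed from Col-0 by 6.01 ± 0.21 and -5.04 ± 0.63, in the direction seen in PIN1-GFP. Further lists passed camera at smaller medians: iron deficiency at 0.93 against PIN1-GFP (adjusted p = 0.0014, and 0.42 with an estimated correlation; 0 called, 8 over the list alone) and 0.74 against Col-0 (0.011; 0.67; 3 called), hypoxia at 0.69 (0.025 and 0.5), jasmonate at 0.39 (0.025 and 0.5), phosphate starvation at -0.26 (0.025 and 0.36), salicylate at 0.35 (0.022 and 0.42), these against PIN1-GFP, and cytokinin at -0.45 against Col-0 (0.017; 0.37; 0 called, 3 over the list alone). Calls were lost without PIN1-GFP control replicate 2 (hypoxia 0.069, jasmonate 0.063), PIN1-GFP control replicate 3 (phosphate 0.072), pig1 control replicate 1 (jasmonate 0.052), pig1 control replicate 2 (salicylate 0.085, cytokinin 0.12), pig1 control replicate 3 (hypoxia 0.06, jasmonate 0.063, phosphate 0.058; against Col-0 detoxification 0.26 and iron 0.06) and Col-0 control replicate 2 (iron 0.12).

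Against PIN1-GFP 502 genes were higher and 391 lower (limma), and against Col-0 397 and 313. The first total of 893 was 406, 468 and 532 without PIN1-GFP control replicates 1, 2 and 3, 594 without moderation and 525 in a fit of the 6 libraries alone. The second total of 710 was 337 and 292 without Col-0 control replicates 1 and 2, and 264 in a fit of the 6 libraries alone. Higher in both were 209 genes, with 14 by chance, and lower in both 184, with 9 by chance. The comparisons share the pig1 control libraries: their covariance across genes was 0.143 against 0.0178 in 20 simulations of unchanged groups, with r = 0.78 against 0.48. The simulations called a mean of 0 genes in both, and since they hold no real effects, part of the excess may still come from the shared libraries.

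The difference of the GR24 effect between pig1 and PIN1-GFP, and between pig1 and Col-0, addresses whether pig1 alters the change from control to GR24 libraries. If the heading t0 holds, that change includes time and incubation, and a difference cannot be assigned to GR24 alone. Heat shock genes rose less in pig1. HSP70-4 differed by -1.99 ± 0.21 from PIN1-GFP (adjusted p = 3.8e-05) and by -1.78 ± 0.21 from Col-0 (adjusted p = 5.8e-05), and the small heat shock protein gene HSP17.6A (AT5G12030) by -3.86 ± 0.65 and -4.22 ± 0.65. Of 11 heat shock genes the difference was lower for 7 against PIN1-GFP (8 adjusted over the list alone, median -1.99, camera adjusted p = 5.5e-06, and adjusted p = 0.2 with an estimated correlation). The number against Col-0 was 5 of 11 (7 adjusted over the list alone, median -1.78, camera adjusted p = 2.5e-05, and adjusted p = 0.29 with an estimated correlation). HSP70-4 reads in PIN1-GFP went from 853 ± 42.1 to 7280 ± 2210 and in pig1 from 1900 ± 295 to 3930 ± 292. Touch genes rose more in pig1. TCH3 differed by 1.19 ± 0.19 and 1.32 ± 0.19, and ZAT12 by 0.93 ± 0.21 and 1.92 ± 0.21. Of 7 touch genes 4 were higher against PIN1-GFP (4 adjusted over the list alone, median 1.19, camera adjusted p = 0.0012, and adjusted p = 0.17 with an estimated correlation). Against Col-0 it was 5 of 7 (6 over the list alone, median 1.4, camera 3.6e-06 and 0.015). The phosphate sensor gene SPX1 (AT5G20150) differed by 2 ± 0.41 and 2.5 ± 0.41. Phosphate starvation genes were higher for 4 of 10 against PIN1-GFP (5 adjusted over the list alone, median 0.72, camera adjusted p = 0.00066, and adjusted p = 0.17 with an estimated correlation). Compared with Col-0, 4 of 10 were higher (4 over the list alone, median 0.76, camera 0.001 and 0.23).

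Some hypoxia genes also differed in their response, with 0 of 11 called in PIN1-GFP minus Col-0. The flavonoid and detoxification lists passed camera only against PIN1-GFP. The desaturase SAD6 (AT1G43800) differed by 2.33 ± 0.41 against PIN1-GFP, and HRE1 (AT1G72360) by 1.84 ± 0.4 against Col-0. Hypoxia genes were higher for 1 of 11 against PIN1-GFP (3 adjusted over the list alone, median 0.96, camera adjusted p = 0.0044, and adjusted p = 0.56 with an estimated correlation). The number against Col-0 was 6 of 11 (9 over the list alone, median 1.42, camera 3e-05 and 0.41). Flavonoid genes were lower for 6 of 14 (6 over the list alone, median -0.66, camera adjusted p = 7.7e-05; 0.21 with an estimated correlation). Detoxification genes were lower for 6 of 26 (10 over the list alone, median -0.46, camera 0.00066 and 0.34), both against PIN1-GFP, with CHI at -0.9 ± 0.16 and GSTF6 at -1.63 ± 0.19. Neither list passed against Col-0, with 1 of 14 flavonoid genes lower (5 over the list alone, median -0.25, camera adjusted p = 0.13) and 3 lower and 1 higher of 26 detoxification genes (3 and 2 over the list alone; -0.19, 0.29). In PIN1-GFP minus Col-0 both lists had medians above 0. The defence genes LURP1 (AT2G14560) and PCC1, higher in pig1 controls, had differences of -8.05 ± 0.74 and -6.59 ± 0.65 against PIN1-GFP. LURP1 had 0, 1.22 and 0.989 reads in PIN1-GFP control replicates 1 to 3, so the size of its difference rests on the pseudocount (-5.76 with a pseudocount of 5). The ethylene response factors ATERF13 (AT2G44840) and AT5G51190 had 4.17 ± 0.78 and 3.91 ± 0.56, and the F-box gene AtPP2-B13 (AT1G56240) 6.13 ± 1.03 against Col-0. Among the strigolactone markers the homeobox gene HB53 (AT5G66700) differed by 2.19 ± 0.39, SMXL2 by 0.93 ± 0.21 and SMXL7 (AT2G29970) by -0.64 ± 0.14, and DLK2 was not called (0.17 ± 0.21, adjusted p = 0.64). AOX1A differed by 0.35 ± 0.14 from PIN1-GFP (adjusted p = 0.12). Against Col-0 it differed by 0.53 ± 0.14, a call lost without Col-0 control replicates 1 (0.053) or 2 (0.059), pig1 GR24 replicates 1 (0.065) or 2 (0.054) or Col-0 GR24 replicate 3 (0.067).

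Smaller shifts of other lists passed camera in these differences. Jasmonate genes were higher for 5 of 13 against Col-0 (10 adjusted over the list alone, median 1.02, camera adjusted p = 0.00041, and adjusted p = 0.45 with an estimated correlation) and for 1 against PIN1-GFP (4 adjusted over the list alone, median 0.73, 0.042; 0.62 with an estimated correlation). The second call was lost without PIN1-GFP control replicates 1 (0.051) and 3 (0.055), pig1 control replicates 2 (0.1) and 3 (0.057), PIN1-GFP GR24 replicate 3 (0.41) and pig1 GR24 replicate 2 (0.16). Root hair genes were lower in pig1 than in PIN1-GFP without and with GR24 (medians -1.14 and -0.49). Their difference had a median of 0.54 against PIN1-GFP (camera adjusted p = 0.028; 0.56 with an estimated correlation; 0 called) and 0.53 against Col-0 (0.019; 0.41; 1 called). The first was lost without PIN1-GFP control replicate 3 (0.072), pig1 control replicate 3 (0.057), PIN1-GFP GR24 replicate 3 (0.19) and pig1 GR24 replicate 2 (0.065), the second without Col-0 GR24 replicate 3 (0.051). Against Col-0 the unfolded protein response had a median of 0.26 (camera adjusted p = 0.02; 0.41 with an estimated correlation) and light-harvesting genes -0.25 (0.045 and 0.56). The first was lost without Col-0 control replicate 2 (0.056), pig1 control replicate 3 (0.072) and Col-0 GR24 replicate 2 (0.063). Light-harvesting genes lost the call without Col-0 control replicates 1 (0.067) and 2 (0.056), pig1 control replicates 1 (0.085) and 3 (0.099), pig1 GR24 replicates 2 (0.17) and 3 (0.078) and Col-0 GR24 replicates 1 (0.059) and 3 (0.084).

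The difference from PIN1-GFP was higher for 634 genes and lower for 475 (limma), and that from Col-0 for 666 and 445. The first total of 1109 was 628 and 709 without PIN1-GFP control replicates 1 and 3, 604 without PIN1-GFP GR24 replicate 1, 556 and 651 without pig1 GR24 replicates 1 and 3, and 694 without moderation. With size factors from total reads 36.3% of 1263 calls were higher in place of 57.2% against PIN1-GFP, and 37.9% of 1355 in place of 59.9% against Col-0. Higher in both differences were 363 genes, with 30 by chance, and lower in both 206, with 15 by chance. The pig1 libraries enter both: the covariance across genes was 0.271 against 0.0368 in 20 simulations of unchanged groups (r = 0.74 against 0.49; a mean of 0 genes called in both), and part of the excess may still come from shared libraries. Over 1141 genes that changed at least 2-fold with GR24 in Col-0 of set 2, the GR24 effect in pig1 minus that in PIN1-GFP averaged -0.07 in the direction of that change (54.4% smaller, fry adjusted p = 0.52, and adjusted p = 2.8e-12 for change in either direction). Minus that in Col-0 it averaged 0.12 (41.7% smaller, fry adjusted p = 0.027, and adjusted p = 2.3e-12 in either direction).

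**Figure D4:**
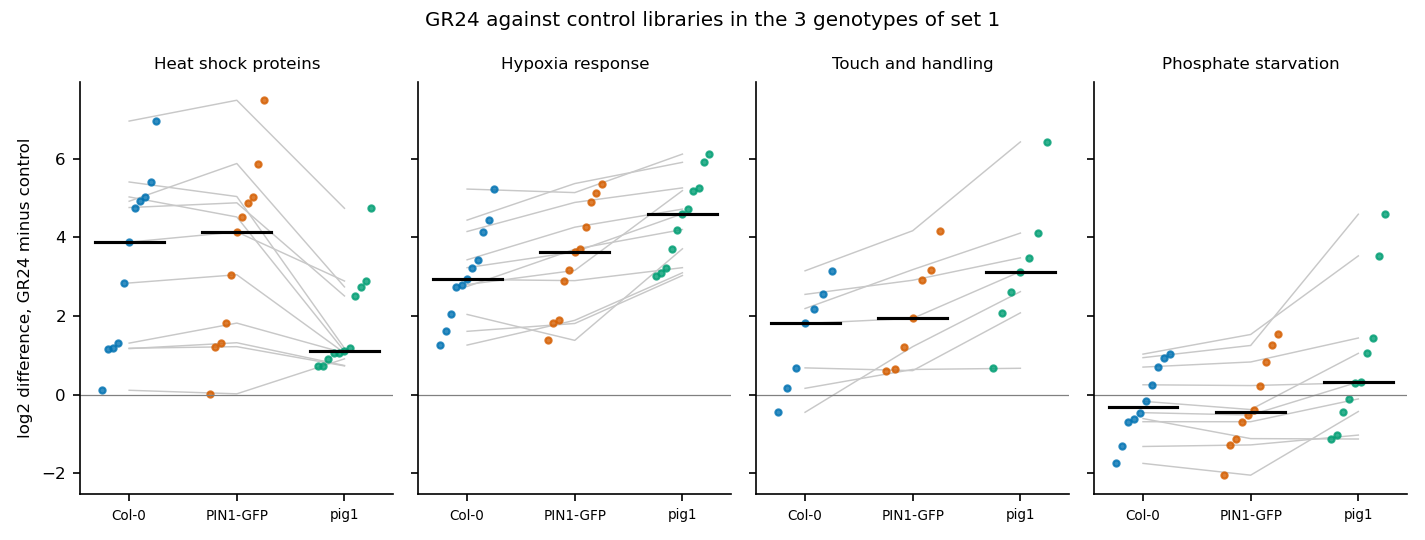
Log2 difference between GR24 and control libraries (vertical axis) of the members of 4 gene lists in Col-0, PIN1-GFP and pig1 of set 1; points are genes joined by grey lines, and bars are medians. Heat shock genes have a median of 4.14 in PIN1-GFP and 1.1 in pig1.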

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

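The tests of clock genes, of the strigolactone response, of the stimulon level in control libraries and of exchanged labels were chosen after the results were seen, as was the comparison of pig1 with PIN1-GFP in GR24.

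The GR24 and control libraries of Col-0 differed in other ways in set 1 than in set 2, with the mitochondrial dysfunction stimulon up in one and not in the other. The strigolactone markers changed by a median of 0.61 less in set 1 than in set 2 (-0.61), and DLK2 by 1.27 less (-1.27). Measured from controls that may be t0, this change cannot decide whether the strigolactone response itself was larger in set 1. In Col-0 GR24 libraries the markers lay lower in set 2 than in set 1 (median -0.58), whereas DLK2 lay higher (712 against 406 CPM), without a test. Clock genes differed by a median size of 1.54 in set 1 and 0.25 in set 2. This argues against set 1 controls matched in time to the GR24 libraries. Another time of collection, as their heading t0 gives, may be the reason. The stimulon lay 4.54 higher in the set 2 controls (4.33 in the lowest pair of libraries), so an incubation that raised it in those controls may also play a part, and the 2 explanations do not exclude each other. With GR24 in set 1 the stimulon lay below the Col-0 acetone libraries of set 2 (median -1.02), and AOX1A had 510 against 1020 CPM. Seedlings without GR24 in set 2 thus had at least the level found with GR24 in set 1, though levels were not tested across the experiments. Treatment and time or incubation are confounded in set 1 if the heading holds, so whether GR24 itself raised the stimulon there stays open.

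Heat shock genes rose less with GR24 in pig1 than in PIN1-GFP. Without pig1 control replicate 1, the library with the most reads, the median difference was -2.04 in place of -1.99, which argues against that library as the cause. In GR24 libraries alone the list was lower in pig1 by a median of -0.91 (4 of 11 genes lower and 1 higher, camera adjusted p = 0.012, and adjusted p = 0.37 with an estimated correlation). At the preset correlation this argues against a higher control level (0.84) as the whole cause, although that level accounts for part of the difference. Root tissue markers, at 0.13 in GR24 libraries, could not tell whether the share of root tissue differed. The list call of the difference was also lost with an estimated correlation, and a biological difference remains a hypothesis. If the heading t0 holds, the difference may concern time or incubation and not GR24. In Col-0 the list lay higher in the set 2 acetone libraries than in the set 1 controls, by a median of 2.75.

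ANAC017 tags were higher in libraries labelled anac017. An exchange of labels is argued against by the stimulon, which was lower in the libraries labelled anac017 by a median of -2.85. The tags of the neighbouring genes were not higher, with differences of -0.19 and -0.15. This cannot decide whether transcripts ran in from a neighbour, since one that ends at ANAC017 may leave its 3′ tags only there. A transcript that starts within or after the insertion may leave 3′ tags and stays open, since the position of the insertion is not in the sources used here.

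The GR24 effect differed between anac017 and Col-0 for 178 genes. Its list medians were 0.44 for abscisic acid, 0.69 for detoxification, 0.31 for early auxin, -0.71 for the unfolded protein response, 0.83 for flavonoids, 0.89 for the stimulon, 0.47 for root hairs, -1.77 for salicylate and defence and -1.3 for sugar starvation genes. UGT74E2 differed by 2.75, FRK1 by -4.37, BIP3 by -5.07 and PER4 by -4.37. BIP3 lost its call without Col-0 acetone replicates 1 (0.05) or 3 (0.051) or anac017 GR24 replicate 2 (0.05). PER4 lost it without Col-0 acetone replicates 1 (0.066) or 3 (0.064), Col-0 GR24 replicates 1 (0.057) or 2 (0.059), anac017 acetone replicate 1 (0.051) or anac017 GR24 replicates 1 (0.059) or 2 (0.06). Of 100 reassignments of genotype within each treatment 6 called as many genes (the real one included), so chance was not excluded. The highest of the others called 1795, which points to a structure of the samples. That structure was not tested and may be the difference between the genotypes itself, since a reassignment in one treatment brings it in. Without Col-0 GR24 replicate 3 the count was 2085.

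Between pig1 and PIN1-GFP the GR24 effect differed for 1109 genes, with medians of -0.46 for detoxification, -0.66 for flavonoid, -1.99 for heat shock, 0.96 for hypoxia, 0.73 for jasmonate, 0.72 for phosphate, 0.54 for root hair and 1.19 for touch genes. LURP1 differed by -8.05 (-5.76 with a pseudocount of 5), PCC1 by -6.59, HSP17.6A by -3.86, ATERF13 by 4.17 and AT5G51190 by 3.91. Between pig1 and Col-0 it differed for 1111 genes, with medians of 0.26 for the unfolded protein response, -1.78 for heat shock, 1.42 for hypoxia, 1.02 for jasmonate, 0.76 for phosphate, -0.25 for light-harvesting, 0.53 for root hair and 1.4 for touch genes. AtPP2-B13 differed by 6.13, LURP1 by -8.05 (-5.29 with a pseudocount of 5, at 0 reads in every Col-0 control library) and HSP17.6A by -4.22. Of 100 reassignments 2 and 4 called as many genes as the real ones. The reassignments also move the difference between the genotypes that is present without GR24, so chance was not excluded by them for the difference of the effect. The highest others, 1821 and 2484, exchanged the genotypes fully in one treatment, and besides these the highest were 695 and 1130.

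Between PIN1-GFP and Col-0 the GR24 effect differed for 3 genes by limma (1540 at an unadjusted p under 0.05), with medians of 0.32 for detoxification, 0.19 for the unfolded protein response, 0.43 for flavonoid, -0.24 for light-harvesting, 0.4 for salicylate and 0.47 for touch genes. ARGAH2 differed by 1.05, NANA by 0.85 and ELIP2 by -1.4. Of 100 reassignments 12 called as many genes, the highest of the others 74, so chance was not excluded.

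In comparisons of 2 groups the 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. The real counts, with the highest other split in brackets, were 9264 (0), 9831 (1) and 9988 (0) for GR24 in Col-0, PIN1-GFP and pig1 of set 1 and 4258 (0) and 2326 (0) for GR24 in Col-0 and anac017 of set 2. They were 893 (0) for pig1 against PIN1-GFP, 710 (1) for pig1 against Col-0, 13 (1) for PIN1-GFP against Col-0, 2941 (0) for anac017 against Col-0 and 1966 (1) for pig1 against PIN1-GFP in GR24.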

How the results depend on the processing

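The settings with other pseudocounts, a mean of 50 reads, other size factors, no moderation, voom weights and deposited scores were chosen after the results were seen. Where compared, no call of a named gene or gene list turned direction. Of 12620 values for named genes 12053 kept their side of the threshold, 486 lost and 81 gained a call, and of 1230 values for gene lists 1040 kept it and 190 lost it.

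With a correlation estimated from the data the number of lists past the threshold dropped in each comparison: GR24 in Col-0 of set 1 from 12 to 2, in PIN1-GFP from 11 to 2, in pig1 from 12 to 3, in Col-0 of set 2 from 7 to 0 and in anac017 from 10 to 1. It went from 9 to 0 for pig1 against PIN1-GFP, 6 to 1 for pig1 against Col-0, 3 to 0 for PIN1-GFP against Col-0, 8 to 0 for anac017 against Col-0 and 7 to 1 for pig1 against PIN1-GFP in GR24. For the differences of the GR24 effect it went from 8 to 0 (pig1 minus PIN1-GFP), 8 to 1 (pig1 minus Col-0), 6 to 0 (PIN1-GFP minus Col-0) and 9 to 0 (anac017 minus Col-0). The wider error of lists whose members vary together is part of this setting.

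Counts of called genes moved under other tests. Without moderation limma called 594 in place of 893 genes for pig1 against PIN1-GFP, 694 in place of 1109 for the difference of the GR24 effect between them, 1 in place of 3 for PIN1-GFP minus Col-0 and 0 in place of 178 for anac017 minus Col-0 (2320 at an unadjusted p under 0.05 in the reported test). With only the groups compared it called 525 for pig1 against PIN1-GFP, 264 in place of 710 for pig1 against Col-0 and 85 in place of 13 for PIN1-GFP against Col-0. On the deposited scores it called 6 for PIN1-GFP against Col-0, and 0 for the differences PIN1-GFP minus Col-0 (1540 at an unadjusted p under 0.05 in the reported test) and anac017 minus Col-0. Voom weights gave 1 for PIN1-GFP minus Col-0 and 61 for anac017 minus Col-0, and size factors from total reads gave 1 for PIN1-GFP minus Col-0. The cause was not tested.

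Leaving out 1 library gave these ranges of called genes. For anac017 minus Col-0 it was 12 (without Col-0 acetone set 2 replicate 3) to 2085 (without Col-0 GR24 set 2 replicate 3), and its lists numbered 5 (without anac017 acetone replicate 3) to 10. For GR24 in Col-0 of set 2 it was 2832 to 5063 (without GR24 replicates 1 and 3), for GR24 in anac017 1474 (without GR24 replicate 2) to 1962 and for anac017 against Col-0 1845 (without Col-0 acetone replicate 3) to 2623. For pig1 against PIN1-GFP it was 406 (without PIN1-GFP control replicate 1) to 974 (without pig1 control replicate 3), for pig1 against Col-0 292 (without Col-0 control replicate 2) to 713, and for pig1 against PIN1-GFP in GR24 1052 (without pig1 GR24 replicate 1) to 1675, with 5 to 12 lists. For pig1 minus PIN1-GFP it was 556 (without pig1 GR24 replicate 1) to 1367 (without pig1 control replicate 3), and for PIN1-GFP minus Col-0 0 (without PIN1-GFP control replicate 2) to 28 (without PIN1-GFP GR24 replicate 3). The lists of PIN1-GFP against Col-0 numbered 2 (without PIN1-GFP control replicate 1) to 5 (without Col-0 control replicate 1). The cause was not tested, though fewer libraries were fitted in each.

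No paired analysis was possible because the columns carry no replicate numbers, so the planned replicate block was not run. The planned DESeq2 Wald test and the planned comparison of RLE with TMM size factors were also not run, since the deposited tables hold scores and the size factors were taken from them.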

Other observations

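The comparison of pig1 with PIN1-GFP in GR24 libraries, and the overlap across tables given here, were chosen after the results were seen. In GR24, ASG1 was higher in pig1 by 4.65 ± 0.25 (adjusted p = 1.8e-09, limma), a gene that was lower in PIN1-GFP than in Col-0 without GR24 (-3.93 ± 0.25). Also higher were the hypoxia genes SAD6 and LBD41 by 2.46 ± 0.29 and 1.7 ± 0.26, the touch genes ZAT12 and TCH2 (AT5G37770) by 1.31 ± 0.15 and 0.82 ± 0.1, SPX1 by 2.24 ± 0.29 and LOX2 by 1.44 ± 0.20. AT5G52970 was lower, at -4.15 ± 0.2, and HSP70-4 at -0.85 ± 0.15. AOX1A was not called (0.11 ± 0.1, adjusted p = 0.48). Touch genes were higher for 5 of 7 (median 1.31, camera adjusted p = 5.2e-06, and adjusted p = 0.021 with an estimated correlation), hypoxia genes for 8 of 11 (1.35, 1.9e-07 and 0.33) and jasmonate genes for 10 of 13 (1.05, 5.3e-06 and 0.33). In total 1213 genes were higher and 753 lower, and the count of 1966 was 1135 without PIN1-GFP GR24 replicate 1, 1052 without pig1 GR24 replicate 1 and 1272 without pig1 GR24 replicate 3. With size factors from total reads 44% of 2108 calls were higher in place of 61.7%.

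Genes that were higher in GR24 than in control libraries of Col-0 in set 1 were often lower in anac017 than in Col-0 of set 2 in acetone. Of 8583 genes tested in both, 892 rose in the first and were lower in the second against 488 by chance, 574 the reverse against 368, 199 were higher in both against 409 and 144 lower in both against 440 (Pearson's r = -0.44 and Spearman's rho = -0.41 across genes, which are not independent replicates). The libraries come from separate tables and the overlap was not tested. If the heading t0 holds, the set 1 change includes time and incubation, so the overlap does not show that genes raised by GR24 depend on ANAC017. The stimulon, lower in anac017, lay 4.54 higher in the Col-0 acetone libraries of set 2 than in the Col-0 controls of set 1.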
